A study of Mus musculus with 35 samples.

How the data were processed

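RNA was measured by 3′ tag sequencing in 35 mouse samples, 6 whole embryos at embryonic day 9.5 and 29 samples of the left hippocampal CA region of adult mice. Per the labels' protocols, the carriers had 1 floxed Setd5 allele and CMV-Cre, a transgene active throughout the body, and they were set beside wild-type animals of the C57BL/6J strain. Libraries were made with the QuantSeq FWD kit from 500 ng of RNA per embryo sample and 1 µg per CA sample, per the labels' protocols. This kit reads from the 3′ end of polyadenylated transcripts on the strand of the gene, so a gene's count does not grow with its length and says little of splice forms or of deletions far from the 3′ end.

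The deposited values were whole-number read counts per gene, 1 table per library, not normalised and not pooled. Alignment and counting used STAR 2.5.4 on GRCm38 (mm10), and R 3.5.0 with edgeR 3.22.2 were also listed, per the submitters' processing notes. The annotation release the authors used is not given in the sources used here. Each table of deposited counts held an unstranded column and 1 column per strand, and the gene-strand column was used (column 3). It held 95.2% to 95.7% of the counts of the strand columns together. The 4 summary lines that name no gene stayed out of library sizes and tests. They gave 30.0% to 43.7% of reads as unmapped and 13.2% to 20.9% as outside genes, with a multimapping count of 0 in all 35 tables. Reads shared between near-identical genes may thus be missing from the counts.

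The tables listed 52550 genes by identifier. Of these, 52403 matched an identifier in GENCODE vM21 (GRCm38), from which symbols and positions were taken, and 147 did not match and were tested without a symbol. Assigned counts per library ran from 6.82 to 8.23 M in embryos and from 5.26 to 10.5 M in the hippocampus. A chi-square comparison of the 62 pairs of libraries within groups, over genes with at least 20 counts, gave 2.21 to 38.8 per degree of freedom, so no pair agreed within sampling noise and every library counted as 1 replicate. Series text calls the replicates biological, and groups were taken from the labels alone.

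Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 13961 genes in the embryo and 14899 in the hippocampus. Libraries were scaled by TMM, and a quasi-likelihood model with robust dispersion was fitted to the 6 embryo libraries and, separately, to the 29 hippocampal libraries with 1 mean per group. Adjusted p-values are from glmQLFTest with Benjamini-Hochberg adjustment over all genes tested, and a gene passed below 0.05. A standard error is the absolute log2 fold change divided by the square root of F. Levels are TMM-normalised CPM, which scale each library to the same total, as mean ± SD over libraries, and log2 CPM used a prior count of 1. Contrasts were heterozygous against wild-type in embryos and in each hippocampal state, their average over the 3 states, 1 h and 3 h after training against home cage and against each other within each genotype, and the genotype-by-training interaction at each time.

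The genotype effect was set against training in a further value, the response size. It is the median interaction over the genes called in the response averaged over genotypes, signed by that response. At 1 h this took 3 genes. At 3 h no gene was called, so the planned value could not be formed, and lists of genes took its place.

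In all, 41 gene lists covering activity-dependent and hormone-induced genes, cell types, embryonic tissues, neighbouring tissues and general cell processes were fixed, 25 for the embryo and 30 for the hippocampus, with some in both. They were tested with camera in limma 3.58.1 at its preset correlation of 0.01, with camera at a correlation estimated from the data, and with fry. Camera compares a list with all other genes. Fry asks whether the members move on balance in 1 direction and compares them with no other gene. Members were also adjusted over the list alone. The genes named are Setd5, then up to 10 called genes in each direction, up to 4 called members of each list or otherwise the 1 or 2 members with the smallest p, and the 3 genes with the smallest p where a comparison had no call. Gene models without a proper name were only counted. Sex-linked genes were treated as a list.

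Single values were compared by two-sided exact permutation tests of the difference in mean log2 CPM (scipy 1.17.1, Python 3.11.15), with Benjamini-Hochberg adjustment over the 26 tests of that family. The smallest p these can give is 0.1 for 3 against 3 libraries, 0.0159 for 4 against 5 and 0.00794 for 5 against 5. A list score is the mean log2 CPM of its members in a library.

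Design, gene lists, naming rule and most alternatives were set before the data were examined. The alternatives were other scalings (DESeq2 size factors, library size only), no filter or a minimum count of 50, an adjusted p of 0.01, DESeq2 1.42.0, limma voom with quality weights, unstranded counts, a replicate block, surrogate variables from sva 3.50.0, covariates for tissue markers or Xist, a fit of only the groups compared, and leaving out each replicate. The tissue covariates were the scores of the dentate gyrus and choroid plexus lists, used in the hippocampus. Surrogate variables numbered 1 in the embryo and 2 of 4 estimated in the hippocampus. Others were chosen after seeing the data. They were a term for technical classes of hippocampal libraries, fits within 2 of these classes, leaving out 3 libraries with high choroid plexus genes, a yolk sac score as covariate, the glucocorticoid list for the response size, and the 4 embryos with Y-linked expression alone.

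The classes were read from the tables. In 9 hippocampal libraries 18.4% to 20.9% of reads lay outside genes, in 5 others Rny1, a small cytoplasmic RNA, stood at 2.60 to 4.71 CPM, and 15 libraries were low in both. All 4 wild-type libraries at 1 h belonged to those 15, while each other hippocampal group held 2 or 3 of them.

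The same steps were tested on simulated counts with the means, spread and library sizes of the real libraries and 200 genes changed by known folds. For E9.5 heterozygous against wild-type embryos, 1.49%, 34.8% and 90.8% of genes changed 1.5-fold, 2-fold and 4-fold were recovered among 13691 genes. For the home-cage genotype comparison these shares were 28.4%, 79.1% and 93.9% among 14782 genes, and for the genotype averaged over 3 states 71.6%, 96.9% and 100% among 14775 genes. For 1 h against home cage in wild-type mice they were 26.9%, 78.8% and 95.5% among 14752 genes. False calls among the unchanged genes of these 4 simulations numbered 12, 3, 3 and 5 in edgeR, 32, 13, 16 and 12 in DESeq2 and 12, 3, 6 and 5 in limma voom. Common biological variation was 23.9% in embryos and 18.6% in the hippocampus.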

Results

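The study asked how loss of 1 copy of Setd5, a gene linked to intellectual disability that encodes a SET domain protein, alters gene expression in the developing embryo and in the adult hippocampus before and after learning. Whole embryos at embryonic day 9.5 (E9.5) comprised 3 wild-type (WT) and 3 heterozygous (het) animals. The CA region of the left hippocampus was taken from mice of 2 to 3.5 months, either from the home cage (5 WT, 5 het) or 1 h (4 WT, 5 het) or 3 h (5 WT, 5 het) after contextual fear conditioning. In this task mice learn to associate a chamber with foot shocks. Training consisted of 120 s of exploration and 3 shocks of 0.5 mA lasting 2 s, spaced 1 min apart. Total gene counts ranged from 6.82 to 8.23 M per embryo library and from 5.26 to 10.5 M per hippocampal library, and 19394 to 21022 genes had at least 1 count.

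Setd5 (chromosome 6, 113077365 to 113153435, plus strand, GRCm38) had lower values in het than in WT samples in every setting, by less than a single silent copy would give. In the hippocampus its level averaged over the 3 states was 142 ± 11.7 CPM in het mice (SD, n = 15) against 173 ± 18.6 CPM in WT mice (n = 14), a fold of 0.815 (95% interval 0.750 to 0.886), or 18.5% lower. By state, Setd5 stood at 141 ± 11.4 against 173 ± 16.1 CPM in the home cage, 141 ± 17.2 against 184 ± 18.4 CPM at 1 h and 143 ± 7.01 against 165 ± 19.9 CPM at 3 h. In embryos it stood at 328 ± 11.5 CPM in 3 het against 367 ± 25.2 CPM in 3 WT animals, a fold of 0.894 (95% interval 0.760 to 1.05). Over all genes, edgeR gave the averaged hippocampal difference an unadjusted p of 1.73e-05 and an adjusted p of 0.197. Exact two-sided permutation tests gave p of 0.0238 in the home cage, 0.0159 at 1 h, 0.0873 at 3 h and 0.200 in the embryo, with adjusted p of 0.155, 0.138, 0.324 and 0.433 over 26 tests. The count is of 3′ tags, and the labels do not say which exons are removed, so tags outside the deleted part would still be counted and the level is no test of the genotype labels. DESeq2 (3 genes), limma voom (4), surrogate variables (5), the class term (2) and library-size scaling (1) each called Setd5 in the averaged comparison, as did edgeR without the WT replicate 3 of 3 h.

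**Figure D1:**
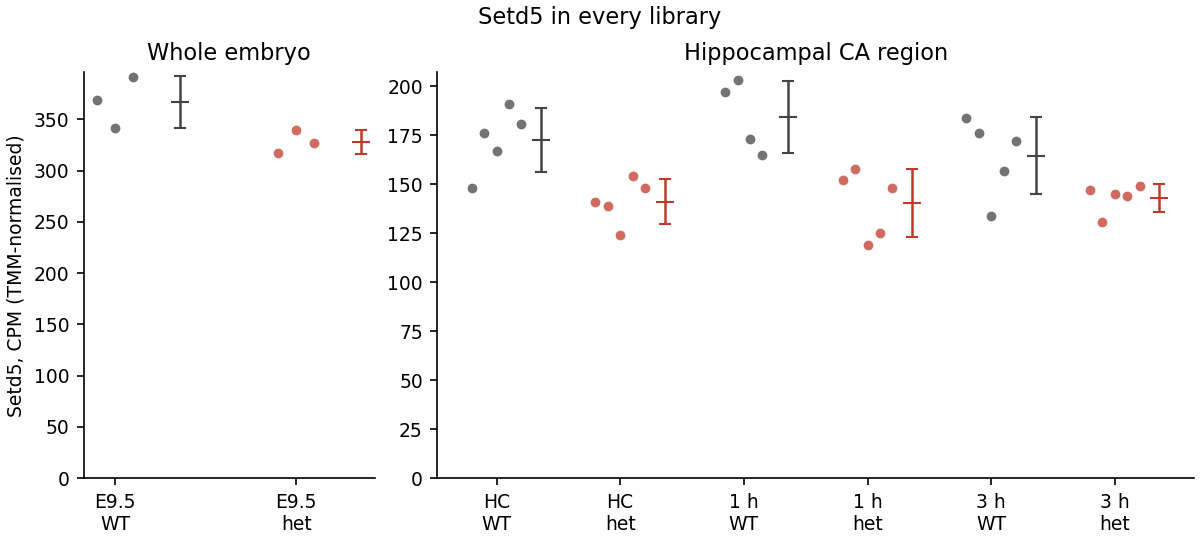
Setd5 in every library, in CPM, for embryos (left) and the hippocampal CA region (right). Points are libraries, and bars give the mean ± SD of each group; averaged over states, het libraries stand at 142 CPM and WT libraries at 173 CPM.

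In E9.5 embryos, most genes of neuronal differentiation had higher values in het than in WT animals, and most cardiac muscle genes had lower ones. Of 40 neuronal genes tested, 37 had higher values in het embryos, with a median log2 fold change of 0.57, and 14 passed when adjusted over the list alone, all higher. Among these were the neurofilament gene Nefm (30.5 ± 2.31 against 15.9 ± 1.40 CPM, SD, n = 3 each, log2 fold change 0.94 ± 0.13 SE), the neuronal tubulin gene Tubb3 (29.6 ± 2.38 against 17.0 ± 1.05 CPM, 0.80 ± 0.13) and the RNA-binding protein gene Elavl3 (35.0 ± 3.50 against 18.9 ± 4.38 CPM, 0.89 ± 0.19). Transcription factors of early neurons lay in the same direction, with log2 fold changes of 1.35 ± 0.36 for Neurod1, 1.15 ± 0.34 for Pou4f1, 1.09 ± 0.27 for Nhlh2, 1.06 ± 0.34 for Neurog1, 0.94 ± 0.29 for Ascl1, 0.86 ± 0.23 for Nhlh1 and 0.62 ± 0.18 for Ebf1. The cytoskeletal genes Ina (0.76 ± 0.21) and Stmn2 (0.56 ± 0.18) lay there too. Elavl3, these factors, Ina and Stmn2 were chosen after their values were seen. Of 32 cardiac muscle genes, 29 had lower values in het embryos, with a median of −0.27, among them the atrial myosin gene Myh6 (43.5 ± 7.34 against 60.0 ± 6.27 CPM, −0.47 ± 0.15) and the tropomyosin gene Tpm1 (−0.21 ± 0.08). No cardiac gene passed over its list alone. The genotypes overlapped in the cardiac list score, as het replicate 3 (5.27 log2 CPM) lay above WT replicates 1 and 3 (5.07 and 5.26).

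Most genes of some other lists also had higher values in het embryos, though single embryos overlapped in part. The list score of WT replicate 3 lay above that of het replicate 2 for progenitors (4.53 and 4.28 log2 CPM) and neural crest (4.36 and 4.21). Scores of ribosomal proteins overlapped as well, and those of cholesterol synthesis and p53 targets did not. For p53 targets the gap was narrow, as WT replicate 2 stood at 4.228 log2 CPM and the het embryos at 4.245 to 4.274. WT replicates 1 and 3, which expressed Xist and not Y-linked genes, stood at 4.016 and 4.012. That score thus parted more by sex-linked expression than by genotype. Of 30 genes of neural progenitors and patterning, 25 had higher values (median 0.32), such as the Notch target Hes5 (221 ± 9.94 against 163 ± 37.8 CPM, log2 fold change 0.43 ± 0.16 SE) and Nkx2-2, a ventral neural tube gene (1.12 ± 0.48). Of 32 genes of neural crest and pharyngeal arches, 27 had higher values (median 0.24), with Dlx2 at 19.3 ± 1.49 against 10.1 ± 3.15 CPM and Barx1, a gene of the arch mesenchyme, at 16.8 ± 3.23 against 9.01 ± 2.38 CPM. Of 24 genes of cholesterol synthesis, 20 had higher values (median 0.20), including Msmo1 (0.27 ± 0.09) and the regulator Srebf2 (0.35 ± 0.12). Values were also higher for 21 of 23 p53 targets (median 0.15), with Zmat3 at 0.30 ± 0.13 and Ccng1 at 0.27 ± 0.13, and for 50 of 74 ribosomal protein genes (median 0.08), with Rpl32 at 0.31 ± 0.09 and Rps15a at 0.19 ± 0.08.

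Camera at its preset correlation gave the neuronal list an adjusted p of 6.72e-34, the cardiac list 4.11e-10, the progenitor list 5.51e-09, the neural crest list 7.19e-07, cholesterol synthesis 4.88e-06, p53 targets 0.00390 and ribosomal proteins 0.0222. None of these calls held when the correlation was estimated from the libraries. The adjusted p with an estimated correlation was then 0.0748 for the neuronal list, 0.584 for the cardiac, progenitor and ribosomal lists, 0.573 for neural crest and 0.181 for cholesterol synthesis and p53 targets, and fry gave the neuronal list an adjusted p of 0.0965. The other 18 lists did not pass in camera, with adjusted p from 0.113 to 0.926. Among them were Hox genes (median −0.11 over 32, Hoxc11 at 0.61 ± 0.30), somite genes (−0.04 over 21, the oscillating genes Lfng at 0.57 ± 0.16 and Hes7 at 0.57 ± 0.22) and the primitive erythroid list (−0.03 over 27, Nfe2 at −0.55 ± 0.42). Endothelium had a median of −0.04 over 28 genes (Eng at 0.28 ± 0.15), gut and liver bud −0.07 over 23 (Onecut1 at 0.69 ± 0.35) and cell cycle genes 0.05 over 38 (Ccnb1 at −0.15 ± 0.07). Clustered protocadherins had a median of −0.07 over 7 genes (Pcdhgb5 at −1.04 ± 0.40) and imprinted genes 0.00 over 33 (Nnat at 0.16 ± 0.12). For the somite list, the gut and liver bud list, the chaperones and some other lists with adjusted p above 0.05 the median and mean, or the median and the test, differed in sign. The clearest such list was the 6 sex-linked genes, with a median of 1.47, a mean of −0.54 and an adjusted p of 0.197.

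Gene by gene, edgeR called 0 of 13961 genes in the embryo at an adjusted p below 0.05, with 317 genes at an unadjusted p below 0.05 where 698 were expected by chance. DESeq2 called 2 genes, Xist and Nefm, and limma voom called 0. The smallest p in edgeR belonged to Nefm, Tubb3 and Dnm3os, an antisense transcript in the Dnm3 gene (43.0 ± 1.31 against 24.6 ± 4.16 CPM, 0.80 ± 0.14), each with an edgeR adjusted p of 0.999. The mean level of the neuronal genes was 3.58 ± 0.13 log2 CPM in het and 3.01 ± 0.15 in WT embryos, and all 3 het embryos lay above all 3 WT embryos (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give, adjusted p = 0.325). Sex differed between the embryos. WT replicates 1 and 3 had Xist at 489 and 567 CPM and at most 3 Y-linked counts, while WT replicate 2 and all 3 het embryos had Y-linked genes at 159 to 164 CPM. Among these 4 Y-expressing embryos, only 1 of them WT, the median of the neuronal list was 0.49, edgeR called 1 gene (Otx2), and p53 targets no longer passed in camera (adjusted p = 0.743). With 1 WT embryo the spread in this fit came from the het embryos alone, so its p-values carry little weight. The p53 call was also lost without WT replicate 3 (camera adjusted p = 0.108), and that of ribosomal proteins without WT replicate 2 or 3 or het replicate 1 or 3 (0.0569 to 0.335). Xist as a covariate ended both calls (camera adjusted p = 0.624 for p53 targets and 0.297 for ribosomal proteins). The ribosomal call also ended among the 4 Y-expressing embryos (0.216), with no filter (0.0655) and with the yolk sac covariate (0.0713). Yolk sac genes, led by Afp, spanned 23.4 to 2846 CPM over the 6 embryos with both genotypes at both ends, and that list did not pass (median −0.11 over 17). In it Prl8a2 stood at 1.65 ± 1.95 and Rhox6 at −0.53 ± 0.96.

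**Figure D2:**
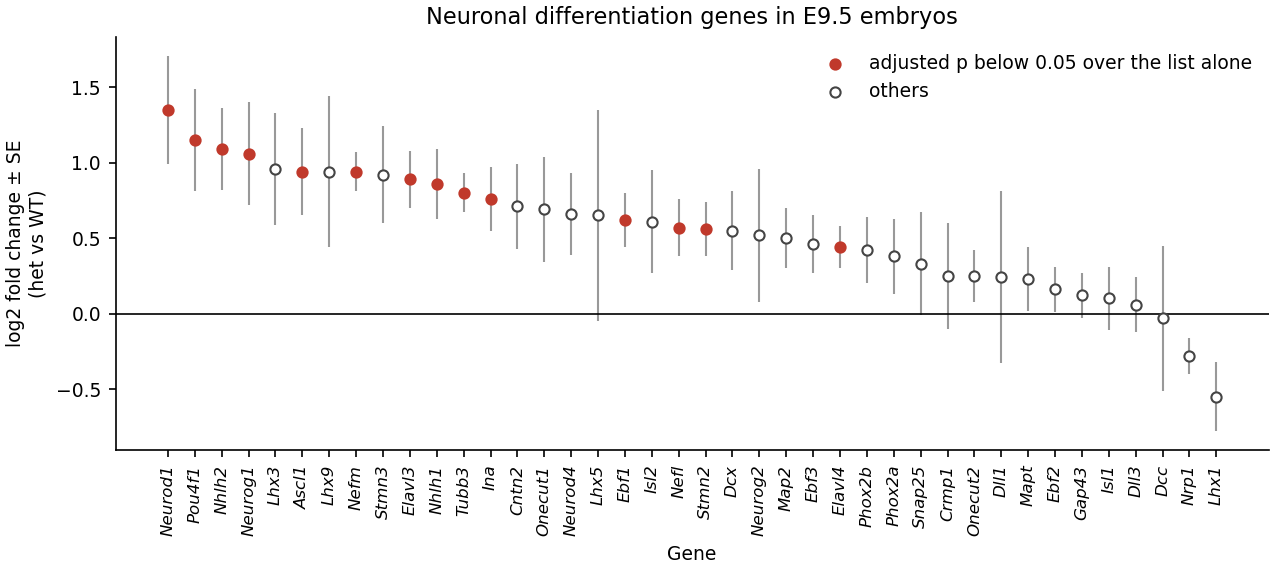
Log2 fold change of het against WT embryos (± SE, n = 3 each) for each of the 40 neuronal differentiation genes tested, ordered by size. Red points are the 14 genes with an adjusted p below 0.05 over the list alone, all higher in het embryos, and 37 of the 40 genes lie above 0.

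Near Setd5 on chromosome 6, the 23 neighbouring genes tested in the embryo had a median log2 fold change of −0.02, with Srgap3 at 0.47 ± 0.16 SE and Tatdn2 at −0.36 ± 0.15. The 12 members of the PAF1 and NCoR complexes, reported partners of SETD5, had a median of −0.05 (Tbl1x at −0.13 ± 0.09), and 53 chromatin regulators of intellectual disability a median of 0.02 (Kdm5c at −0.20 ± 0.09). In the hippocampus averaged over states the same lists had medians of 0.02 over 28 genes (Prrt3 at 0.14 ± 0.07), −0.03 over 12 (Hdac3 at 0.14 ± 0.10) and −0.02 over 54 (Hdac8 at −0.15 ± 0.08). None passed in camera in either tissue. Genotype effects in the embryo and the home-cage hippocampus had a Spearman correlation of 0.150 across 12356 genes, and 0.234 across the 5871 genes with a mean of at least 4 log2 CPM in both. Pearson correlations were 0.088 and 0.136. Against the hippocampal effect averaged over states, Spearman correlations were lower, at 0.117 and 0.178, and Pearson correlations were 0.079 and 0.137. An unadjusted p below 0.05 in both the embryo and the home cage was found for 5 and 2 genes, where 4.2 and 0.8 were expected by chance. Of these, 4 and 1 had the same sign. Genes are not independent replicates, so no p is attached.

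In the hippocampus of home-cage mice, the question was whether the genotypes differ at rest. The genes with the smallest p were Dock8, a guanine nucleotide exchange factor of immune cells, at 2.42 ± 0.136 against 1.12 ± 0.187 CPM (SD, n = 5 each, log2 fold change 1.11 ± 0.27 SE), Tnfsf13b and Sept1. The B cell cytokine gene Tnfsf13b stood at 0.458 ± 0.245 against 1.45 ± 0.590 CPM (−1.60 ± 0.44) and the septin gene Sept1 at 3.77 ± 1.06 against 2.35 ± 0.338 CPM (0.69 ± 0.20). Genes of the meninges had higher values in het mice in 15 of 16 cases (median 0.39), such as Slc6a20a (9.56 ± 3.64 against 5.99 ± 1.18 CPM) and Foxc1 (9.83 ± 1.57 against 7.87 ± 0.664 CPM). Of 21 p53 targets, 18 had higher values (median 0.13), with Dglucy at 0.36 ± 0.19 and Pmaip1 at 0.70 ± 0.42. Choroid plexus genes were higher in 16 of 17 cases (median 1.96), which rested on het replicate 1 with 7444 CPM of Ttr, a carrier of thyroid hormone, against 8.91 to 25.7 CPM in the other 4 het libraries (log2 fold change 7.55 ± 2.63 for Ttr, 5.22 ± 2.22 for Clic6). Of 46 immediate early genes 35 had higher values (median 0.09), though Trib1 (−0.34 ± 0.15) and Gadd45b (−0.44 ± 0.21), those with the smallest p, were lower.

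EdgeR called 0 of 14899 genes in this comparison, with 283 at an unadjusted p below 0.05, and DESeq2 and limma voom called 0 as well. Camera gave the meninges list an adjusted p of 2.41e-04, choroid plexus 0.00115 and p53 targets 0.00794. With an estimated correlation the adjusted p was 0.626, 0.686 and 0.0995. Without het replicate 1 the choroid plexus call ended (camera adjusted p = 0.670). The meninges call ended with tissue covariates (0.182) and in the 15 libraries low in both technical measures (0.0999). The p53 call was lost in 5 alternatives, up to 0.277 in those 15 libraries. The other 26 lists had camera adjusted p from 0.0747 to 0.932, and for oxidative phosphorylation, oligodendrocyte markers, chaperones and a few other such lists the median, mean and test differed in sign.

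At 1 h after training, het and WT mice were compared to see whether the early response differs in level. Genes of oxidative phosphorylation had higher values in het mice in 59 of 72 cases (median 0.12), such as Uqcrq (285 ± 30.7 against 230 ± 13.9 CPM, SD, n = 5 and 4, log2 fold change 0.31 ± 0.12 SE) and Ndufb7 (0.28 ± 0.13). Of 46 immediate early genes, 28 had lower values in het mice (median −0.08), with Egr4 at 62.6 ± 10.3 against 108 ± 9.04 CPM (−0.79 ± 0.34) and the phosphatase gene Dusp5 at 19.6 ± 4.28 against 27.0 ± 3.01 CPM (−0.46 ± 0.21). The genes with the smallest p were the Notch ligand Jag1 (5.59 ± 1.30 against 9.06 ± 1.11 CPM, −0.71 ± 0.17), Ccnjl (−0.84 ± 0.21) and Mc4r, the melanocortin receptor gene (6.90 ± 1.42 against 12.7 ± 0.510 CPM, −0.88 ± 0.23). Metallothionein Mt1 stood at 743 ± 106 against 555 ± 56.1 CPM (0.42 ± 0.15) and Rhob, a small GTPase gene, at 130 ± 22.7 against 168 ± 11.3 CPM (−0.37 ± 0.14).

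Of 14899 genes, 0 passed in edgeR at 1 h (698 at an unadjusted p below 0.05), and 0 in DESeq2 and in limma voom. Oxidative phosphorylation passed in camera with an adjusted p of 8.82e-04, but not with an estimated correlation (adjusted p = 0.903) nor without het replicate 3 (0.0627). Immediate early genes had a camera adjusted p of 0.0567 and the other 27 lists 0.0693 to 0.969. All 4 WT libraries at 1 h were low in both technical measures, against 2 of 5 het libraries, so the comparison at 1 h is partly one of technical classes.

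At 3 h after training, endothelial and immediate early genes had higher values in het than in WT mice, and chaperones and oxidative phosphorylation genes lower. Of 25 endothelial and mural markers, 19 were higher (median 0.20), with the VEGF receptor gene Kdr at 23.5 ± 3.24 against 17.4 ± 3.70 CPM (SD, n = 5 each) and Egfl7 at 64.1 ± 14.2 against 45.9 ± 10.7 CPM. Of 46 immediate early genes, 35 were higher (median 0.16), with Junb at 73.2 ± 14.6 against 58.7 ± 3.87 CPM and Midn at 74.3 ± 9.31 against 62.4 ± 4.40 CPM. Chaperones were lower in 20 of 28 cases (median −0.14), with Dnaja1 at 91.9 ± 6.12 against 107 ± 4.11 CPM, and oxidative phosphorylation genes in 52 of 72 cases (median −0.08), with Ndufb9 at 448 ± 27.4 against 519 ± 46.5 CPM. Hspb1, a small heat shock protein gene, had a log2 fold change of −0.56 ± 0.26 and Ndufv3 one of −0.23 ± 0.10. In the delayed activity list, Bdnf (0.30 ± 0.15) and Vgf (0.29 ± 0.14), genes of secreted growth factors, had the smallest p. The genes with the smallest p were the trafficking GTPase gene Rab1b (45.8 ± 8.12 against 30.9 ± 3.57 CPM, log2 fold change 0.57 ± 0.13 SE), the substance P receptor gene Tacr1 (−1.28 ± 0.32) and Nabp2, a gene of single-stranded DNA binding (0.40 ± 0.11).

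EdgeR called 0 of 14899 genes at 3 h (522 at an unadjusted p below 0.05), DESeq2 called 0, and limma voom called 1, Rab1b. Camera adjusted p was 0.00213 for endothelial markers and for oxidative phosphorylation, 0.00350 for chaperones and 0.0123 for immediate early genes. With an estimated correlation it was 0.450 for endothelial markers and chaperones and 0.815 for the other pair. Single libraries ended each of these calls. They were het replicate 5 for endothelial markers (0.278) and chaperones (0.101), WT replicate 3 for oxidative phosphorylation (0.404) and chaperones (0.136), and het replicate 1 for oxidative phosphorylation (0.0612). For immediate early genes they were WT replicate 1, het replicate 4 or het replicate 5 (0.166, 0.0973 and 0.121). Their call also ended with surrogate variables (0.257), with the class term (0.0847) and without the 3 libraries with choroid plexus transcripts (0.259), and that of chaperones in the 15 libraries low in both technical measures (0.275). The other 25 lists had camera adjusted p from 0.0864 to 0.930.

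Averaging the genotype effect over the 3 states used all 29 hippocampal libraries and asked how the genotypes differ on average. A difference in the average need not be present in each state. After Setd5, the smallest p belonged to Mc4r, at 6.82 ± 1.98 CPM in het against 10.5 ± 2.41 CPM in WT mice (SD, n = 15 and 14, log2 fold change −0.64 ± 0.13 SE), and to the complement gene C4b, at 9.08 ± 1.52 against 6.12 ± 1.64 CPM (0.56 ± 0.12). Of 21 microglia markers, 17 had higher values (median 0.06), such as the protease gene Ctss (58.4 ± 8.55 against 50.6 ± 4.82 CPM) and Siglech (0.32 ± 0.12). Of 22 astrocyte markers 14 had higher values (median 0.06), and Gfap, the astrocyte intermediate filament gene, passed over the list alone (84.0 ± 15.2 against 66.6 ± 7.68 CPM, 0.32 ± 0.08, edgeR adjusted p = 0.00558 over the list alone). Endothelial markers were higher in 20 of 25 cases (median 0.08), p53 targets in 16 of 21 (median 0.07) and choroid plexus genes in 16 of 17 (median 0.76). Among clustered protocadherins, which give neurons their surface identity, Pcdhb11 (0.66 ± 0.19) and Pcdhb16 (−0.43 ± 0.13) passed over the list alone in opposite directions, and among dentate gyrus markers Crlf1 did (0.34 ± 0.10). The imprinted gene Nnat stood at 684 ± 98.0 against 584 ± 85.2 CPM in a list with a median of −0.01 over 31 genes. Further members with the smallest p in their lists were the clotting factor gene F3 (0.69 ± 0.29) among astrocyte markers, Vtn (0.14 ± 0.06) and Ly6a (0.18 ± 0.09) among endothelial and mural markers, and the apoptosis genes Pmaip1 (0.54 ± 0.25) and Fas (0.42 ± 0.21) among p53 targets. In lists that did not pass these were Egr2 (−0.50 ± 0.24) and Egr3 (0.23 ± 0.11), the synaptic gene Snap25 (0.25 ± 0.11), the interferon-induced gene Isg15 (0.64 ± 0.25), the striatal gene Drd2 (0.66 ± 0.25) and, among interneuron markers, Tac1 (−0.21 ± 0.08).

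EdgeR called 0 of 14899 genes in this average (420 at an unadjusted p below 0.05). DESeq2 called 3 (Setd5, Mc4r, C4b) and limma voom 4 (C4b, Doc2a, Setd5, Mc4r). The edgeR adjusted p was 0.197 for Mc4r and 0.291 for C4b, and without WT replicate 1 of 3 h edgeR called C4b. Camera adjusted p was 0.00766 for microglia, 0.0225 for endothelial markers, 0.0386 for astrocyte markers and for p53 targets, and 0.0486 for choroid plexus. With an estimated correlation these were 0.437, 0.638, 0.437, 0.374 and 0.816. The microglia call was lost without het replicate 5 of 1 h (0.0501), the endothelial call in 4 of 29 refits that leave out a library (highest 0.222, without het replicate 5 of 3 h), and the astrocyte, p53 and choroid plexus calls in 10, 11 and 11 of them. The other 24 lists had camera adjusted p from 0.0572 to 0.969.

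The response to training was read within each genotype. In WT mice, most immediate early genes, the transcripts that neurons switch on within minutes of activity, had higher values 1 h after training. Of 46, 37 had higher values (median log2 fold change 0.25) and 9 passed over the list alone. Egr2, an activity-induced zinc finger transcription factor gene, rose 5.01-fold, from 0.866 ± 0.260 CPM in the home cage (SD, n = 5) to 4.44 ± 0.759 CPM (n = 4), and was the 1 gene that edgeR called among 14899 (log2 fold change 2.32 ± 0.39 SE, adjusted p = 0.0235). Junb stood at 106 ± 13.2 against 60.9 ± 13.3 CPM (0.79 ± 0.15), Fos at 13.4 ± 2.70 against 3.57 ± 1.67 CPM (1.88 ± 0.40), Fosb at 7.95 ± 0.954 against 3.40 ± 0.873 CPM (1.22 ± 0.29) and Egr4 at 108 ± 9.04 against 44.5 ± 20.2 CPM (1.27 ± 0.34). Dusp5 (0.84 ± 0.21), Egr1 (0.68 ± 0.19), the clock gene Per1 (0.58 ± 0.21) and Jun (0.33 ± 0.11) also passed over the list alone, and all these genes but Egr2 and Per1 were named after their values were seen. Glucocorticoid-induced genes, which respond to the stress hormone corticosterone, had higher values in 25 of 32 cases (median 0.21), with Rhob at 168 ± 11.3 against 106 ± 17.2 CPM (0.67 ± 0.14, passing over the list alone) and the NF-κB inhibitor gene Nfkbia at 114 ± 11.5 against 80.6 ± 15.8 CPM (0.50 ± 0.16).

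In edgeR 793 genes had an unadjusted p below 0.05 in this comparison. DESeq2 called 5 genes and limma voom 14. The call of Egr2 was lost without home-cage WT replicate 2, 3 or 4 or without any of the 4 WT libraries at 1 h. It was also lost at an adjusted p of 0.01 and among the 15 libraries low in both technical measures. Each of these left 0 genes. A minimum count of 50 left 0 genes as well, but that filter removed Egr2 for its low level before testing. It is thus no test of that call. Without home-cage WT replicate 5, edgeR called 3. Camera gave immediate early genes an adjusted p of 7.92e-15 and glucocorticoid-induced genes 1.68e-07, against adjusted p = 0.0693 and 0.347 with an estimated correlation. The mean of the immediate early genes was 4.65 ± 0.05 log2 CPM at 1 h (n = 4) and 4.26 ± 0.17 in the home cage (n = 5), with a two-sided exact permutation p of 0.0159 (adjusted p = 0.138). Delayed activity genes (median 0.01 over 41), clock genes (0.10 over 21) and glutamatergic synapse genes (0.01 over 56) did not pass, though in the last list Syngap1 had a log2 fold change of 0.78 ± 0.22 and Grin1 one of −0.57 ± 0.20. Nptx1 (0.26 ± 0.13) and Arpp21 (−0.30 ± 0.15) of the delayed genes and the interneuron gene Crhbp (−0.63 ± 0.20) had the smallest p in their lists. Setd5 itself stood at 0.10 ± 0.10. The other 27 lists in all had camera adjusted p from 0.121 to 0.995, with some differing in sign between median, mean and test.

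In het mice at 1 h, Egr2 again had the smallest p, at 2.65 ± 1.33 against 0.811 ± 0.774 CPM (SD, n = 5 each, log2 fold change 1.77 ± 0.39 SE). Of 46 immediate early genes, 32 had higher values than in the home cage (median 0.12), and Egr2, Junb (90.6 ± 8.13 against 62.7 ± 13.3 CPM, 0.53 ± 0.14) and Trib1 (37.0 ± 6.48 against 26.6 ± 5.74 CPM, 0.48 ± 0.15) passed over the list alone. Fos stood at 11.4 ± 7.44 against 5.29 ± 2.12 CPM (1.12 ± 0.37), Egr4 at 62.6 ± 10.3 against 51.2 ± 19.6 CPM (0.29 ± 0.33) and Rhob at 130 ± 22.7 against 132 ± 14.9 CPM (−0.03 ± 0.13). Fosb stood at 0.74 ± 0.27, Egr1 at 0.47 ± 0.18, Dusp5 at 0.31 ± 0.20, Per1 at 0.22 ± 0.20 and Jun at −0.01 ± 0.10. All of these but Egr2 and Junb were named here after their values were seen. Glucocorticoid-induced genes had higher values in 24 of 32 cases (median 0.15), with the kinase gene Map3k6 at 2.54 ± 0.571 against 1.16 ± 0.643 CPM. Sv2c, a synaptic vesicle gene in the delayed activity list, stood at 43.0 ± 7.08 against 29.3 ± 5.59 CPM (0.55 ± 0.15) and passed over that list alone, while Nefm of that list stood at 0.29 ± 0.12. Next to Egr2 in p were Lemd3, a nuclear envelope gene (−0.40 ± 0.10), and the transcription factor gene Cebpg (−0.36 ± 0.09), and Setd5 stood at −0.01 ± 0.10.

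No gene passed in edgeR in het mice at 1 h (0 of 14899, 468 at an unadjusted p below 0.05), nor in DESeq2 (0) or limma voom (0). Without home-cage het replicate 2, whose Egr2 level was 2.15 CPM against 0.269 to 0.807 CPM in the other 4 libraries, edgeR called 1 gene, Egr2. Camera adjusted p was 1.62e-04 for both immediate early and glucocorticoid-induced genes (adjusted p = 0.847 with an estimated correlation). It rose to 0.0727 and 0.294 for immediate early genes without het replicate 3 or 4 of 1 h, and to 0.0689 for glucocorticoid-induced genes without replicate 4. Both calls ended in the 15 libraries low in both technical measures (0.105 and 0.529) and in the 9 with a high share outside genes (0.893, with the sign turned, and 0.468). Choroid plexus genes were lower in 16 of 17 cases (median −2.01, camera adjusted p = 4.97e-04, and 0.847 with an estimated correlation), a call that ended without home-cage het replicate 1 (0.557). The mean of the immediate early genes was 4.49 ± 0.30 log2 CPM at 1 h and 4.35 ± 0.12 in the home cage (n = 5 each, two-sided exact permutation p = 0.373, adjusted p = 0.606). The other 26 lists had camera adjusted p from 0.0519 to 0.933.

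**Figure D3:**
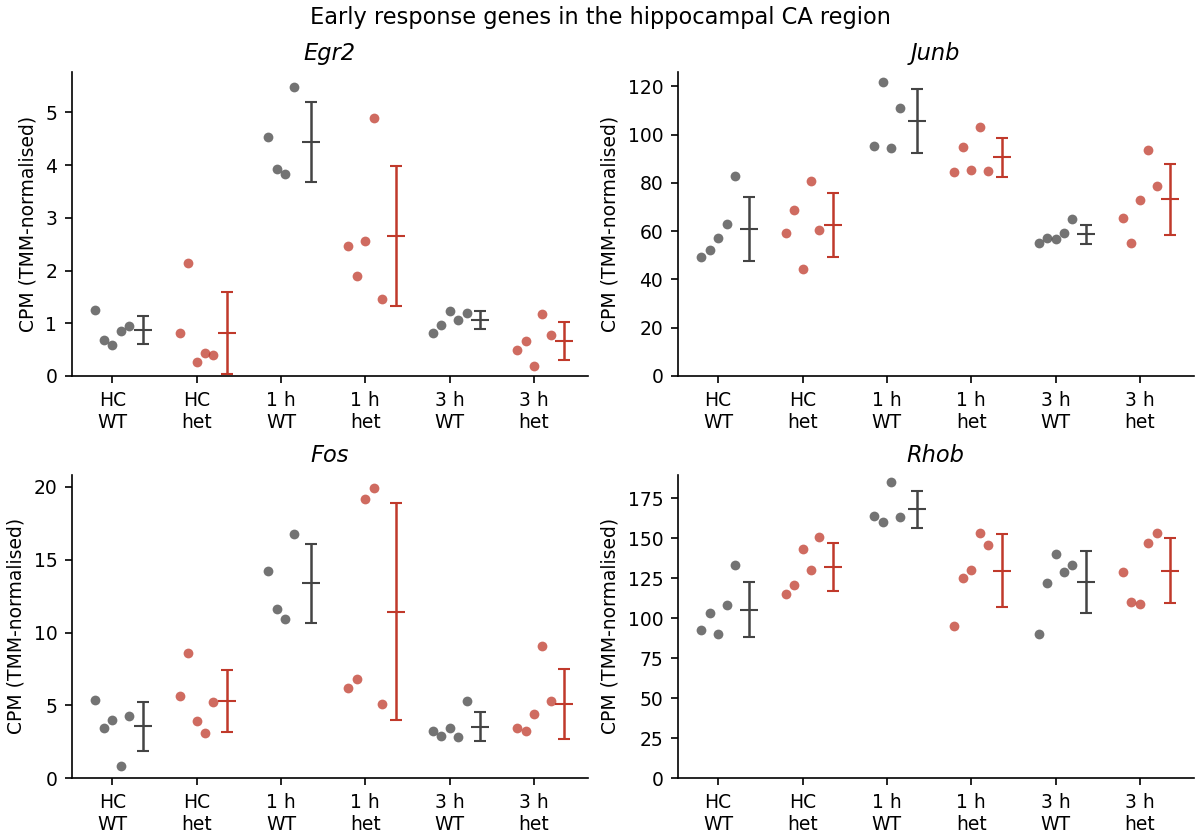
Egr2, Junb, Fos and Rhob in every hippocampal library, in CPM, by state and genotype. Points are libraries and bars give the mean ± SD; Egr2 stands at 4.44 CPM in WT and 2.65 CPM in het mice at 1 h, against 0.866 and 0.811 CPM in the home cage.

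Whether the genotypes responded differently at 1 h was tested by the interaction, which compares the change in het mice with the change in WT mice. Of 46 immediate early genes, 35 had a negative interaction (median −0.21), and 30 had a smaller change in het mice when signed by the response averaged over genotypes (median −0.18). Among these genes, Egr2 stood at −0.55 ± 0.58 (SE, on the log2 scale), Junb at −0.26 ± 0.21, Fos at −0.76 ± 0.55, Fosb at −0.48 ± 0.40 and Jun at −0.34 ± 0.15. Gadd45b, at 0.75 ± 0.31, went the other way. Setd5 had an interaction of −0.10 ± 0.14. Rhob had an interaction of −0.70 ± 0.19 and passed over the glucocorticoid list alone (adjusted p = 0.0358 in edgeR). Oxidative phosphorylation genes had a positive interaction in 54 of 72 cases (median 0.11), with Uqcrq at 0.34 ± 0.16 and Uqcrc1 at 0.26 ± 0.12, and all 16 meninges genes a negative one (median −0.40), with Slc22a6 at −1.37 ± 0.67 and Foxc1 at −0.39 ± 0.20. The meninges score differed mainly in the home cage (2.90 ± 0.37 log2 CPM in het, 2.51 ± 0.31 in WT) and less at 1 h (2.61 ± 0.46 and 2.73 ± 0.53). This interaction thus largely repeats the home-cage difference. Choroid plexus genes had a negative interaction in 15 of 17 cases (median −1.91), with 1 library holding this tissue's transcripts in the home-cage het group. The genes with the smallest p were Rbms2 (−1.33 ± 0.34), Flywch1 (1.41 ± 0.37) and Tnfsf13b (2.39 ± 0.65). Tnfsf13b was also among the genes with the smallest p in the home cage, whose libraries enter the interaction.

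No interaction passed gene by gene at 1 h, with 0 of 14899 in edgeR (512 at an unadjusted p below 0.05), 0 in DESeq2 and 0 in limma voom. Camera adjusted p was 0.00998 for meninges, 0.0126 for immediate early genes, 0.0130 for oxidative phosphorylation and 0.0273 for choroid plexus, all at 0.906 with an estimated correlation, and the other 25 lists had 0.296 to 0.957. For immediate early genes it was lost with surrogate variables (0.951), with tissue covariates (0.0559), with a term for technical class (0.0889), within the 15 libraries low in both measures (0.363), and without home-cage het replicate 2 (0.0608) or het replicate 1 or 5 of 1 h (0.0561 and 0.129). The oxidative phosphorylation, meninges and choroid plexus calls were lost in 6, 3 and 5 of 19 refits that leave out a library, at up to 0.214, 0.370 and 0.787. Averaged over genotypes, edgeR called 3 genes at 1 h, Egr2 (2.05 ± 0.28, adjusted p = 4.82e-04), Junb (0.66 ± 0.10, adjusted p = 0.00430) and Fos (1.50 ± 0.27, adjusted p = 0.0325). Their median interaction, the response size at 1 h, was −0.55 (fry p = 0.124), and their mean level at 1 h was 3.72 ± 0.52 log2 CPM in 5 het against 4.21 ± 0.18 in 4 WT mice (two-sided exact permutation p = 0.143, adjusted p = 0.413). Response size lay between −0.71 and −0.22 when single libraries were left out, lowest without home-cage WT replicate 1 and nearest to 0 without home-cage het replicate 2. Both ends used Egr2, Junb and Fos, and other refits the 2 to 4 genes called in them.

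At 3 h most genes of the glucocorticoid response had higher values than in the home cage in WT and het mice, though in het mice the list passed only in camera at its preset correlation. In WT mice 26 of 32 had higher values (median log2 fold change 0.23) and 6 passed over the list alone. They included the lipid droplet gene Plin4 (6.57 ± 2.27 against 1.70 ± 0.841 CPM, SD, n = 5 each, 1.90 ± 0.45 SE), the lipid transporter gene Mfsd2a (28.9 ± 4.79 against 19.5 ± 3.25 CPM, 0.57 ± 0.14) and the phagocytic receptor gene Mertk (122 ± 19.3 against 86.8 ± 5.74 CPM, 0.49 ± 0.13). The others were Sult1a1 (1.02 ± 0.32), Tsc22d3 (0.49 ± 0.17) and the glucose transporter gene Slc2a1 (0.37 ± 0.13). In het mice 25 of 32 had higher values (median 0.20), and Plin4 (7.62 ± 4.19 against 2.67 ± 1.57 CPM, 1.55 ± 0.43) and Mertk (107 ± 4.67 against 78.0 ± 16.4 CPM, 0.46 ± 0.13) passed over the list alone. Mfsd2a (0.23 ± 0.14), Sult1a1 (0.39 ± 0.31) and Tsc22d3 (0.34 ± 0.17) did not in het mice. Sult1a1 and Tsc22d3, and Mfsd2a in het mice, were named after their values were seen. Immediate early genes were back near their home-cage level, with medians of −0.03 in WT and 0.02 in het mice over 46 genes. In that list Gadd45b stood at −0.50 ± 0.21 in WT and Klf2 at 0.53 ± 0.24 in het mice, and Bach2, a delayed gene, at −0.34 ± 0.13 in WT mice. In het mice Slc2a1 stood at 0.26 ± 0.13 and Tnfsf13b, with the smallest p of all genes, at 1.60 ± 0.44. Setd5 stood at −0.07 ± 0.10 in WT and 0.02 ± 0.10 in het mice.

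EdgeR called 0 of 14899 genes at 3 h against home cage in either genotype, with 246 (WT) and 363 (het) at an unadjusted p below 0.05, and DESeq2 and limma voom called 0 in both. Camera gave the glucocorticoid list an adjusted p of 4.84e-17 in WT and 1.15e-07 in het mice. With an estimated correlation the call held in WT mice (adjusted p = 0.0322), the 1 of 372 list tests in the 13 comparisons that did, and not in het mice (0.615), and fry gave adjusted p of 0.336 and 0.982. The het call was lost without het replicate 5 of 3 h (0.172). List means differed by 0.27 in WT (4.56 ± 0.18 against 4.30 ± 0.16 log2 CPM, n = 5 each, two-sided exact permutation p = 0.0397, adjusted p = 0.206) and by 0.20 in het mice (4.59 ± 0.30 against 4.39 ± 0.14, n = 5 each, exact permutation p = 0.183, adjusted p = 0.431).

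**Figure D4:**
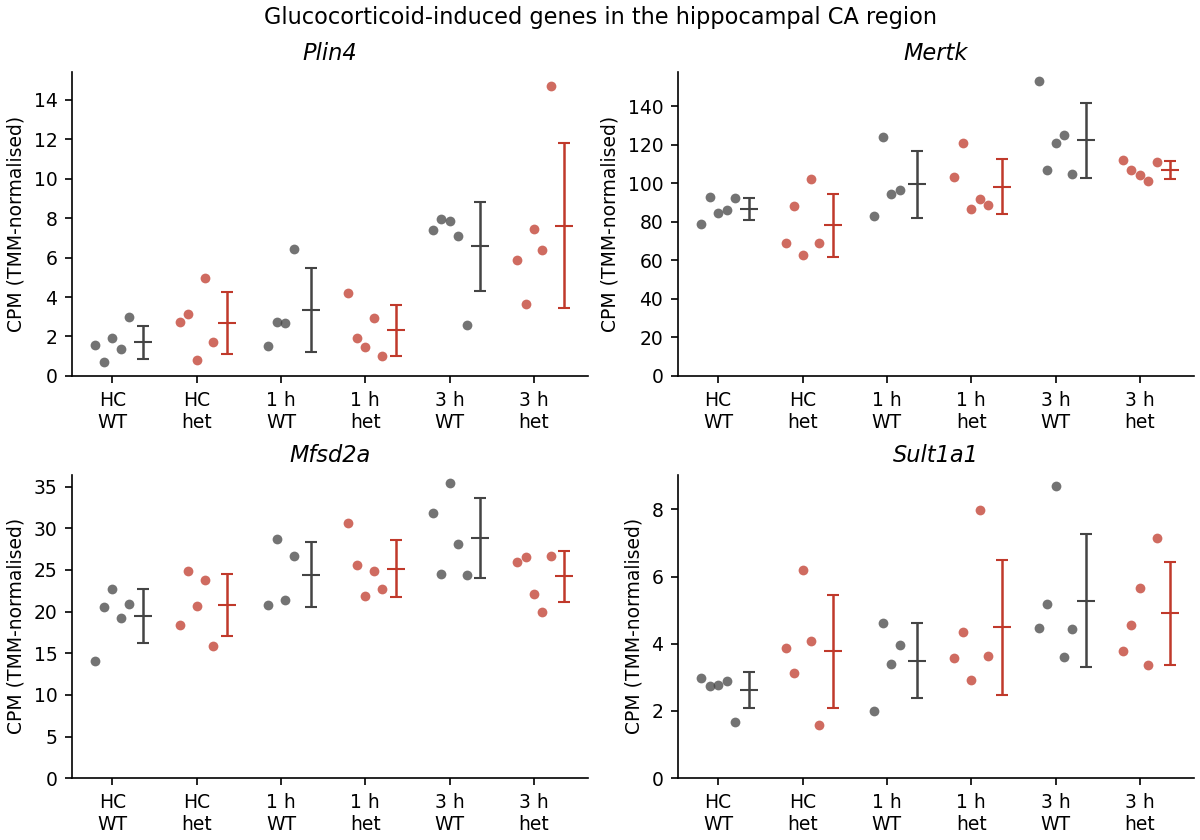
Plin4, Mertk, Mfsd2a and Sult1a1, genes induced by glucocorticoids, in every hippocampal library, in CPM. Points are libraries and bars give the mean ± SD; Plin4 stands at 6.57 CPM in WT and 7.62 CPM in het mice at 3 h, against 1.70 and 2.67 CPM in the home cage.

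Further groups had higher values in WT mice at 3 h than in the home cage, by small amounts. Oxidative phosphorylation genes were higher in 63 of 72 cases (median 0.08, camera adjusted p = 1.43e-05), with Ndufv3 at 155 ± 11.2 against 130 ± 8.81 CPM (SD, n = 5 each). Chaperones were higher in 24 of 28 cases (median 0.11, camera adjusted p = 0.00134). Hspa5, the main chaperone of the endoplasmic reticulum, stood at 673 ± 154 against 526 ± 37.4 CPM and its partner Creld2 at 4.69 ± 1.99 against 3.17 ± 0.847 CPM. Camera also passed choroid plexus (13 of 17, median 1.89, adjusted p = 0.00164), meninges (13 of 16, median 0.32, adjusted p = 0.00224), the interferon response with Ifi27 at 0.39 ± 0.17 (18 of 23, median 0.16, adjusted p = 0.00619) and dentate gyrus markers (17 of 21, median 0.12, adjusted p = 0.0109). Ribosomal proteins (51 of 70, median 0.07) and hypoxia and glycolysis genes (24 of 31, median 0.04) passed in camera at adjusted p = 0.0307. With an estimated correlation the adjusted p of these 8 lists ran from 0.280 to 0.657. Without WT replicate 2 of 3 h, which held 7348 CPM of Ttr, the choroid plexus, meninges, interferon and dentate gyrus calls ended (camera adjusted p = 0.945, 0.204, 0.385 and 0.207). Without WT replicate 3 of 3 h those of oxidative phosphorylation and hypoxia genes ended (0.244 and 0.522), as did that of ribosomal proteins. Of these 8 lists only the chaperones passed in all 10 refits that leave out a library. Within the 15 libraries low in both technical measures none of the 8 passed (camera adjusted p from 0.115 to 0.867, chaperones at 0.718). In het mice none of these lists passed at 3 h, and the 28 lists other than the glucocorticoid one had camera adjusted p from 0.0888 to 0.994. The other 20 lists in WT mice had camera adjusted p from 0.111 to 0.980.

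The interaction at 3 h was negative for chaperones in 23 of 28 cases (median −0.16), with Dnaja1 at −0.26 ± 0.15 (SE, on the log2 scale) and Creld2 at −0.62 ± 0.33. The same held for oxidative phosphorylation in 52 of 72 cases (median −0.11), with Ndufv3 at −0.23 ± 0.14 and Cox7a1 at −0.66 ± 0.38. Setd5 stood at 0.09 ± 0.14. Endothelial markers had a positive interaction in 18 of 25 cases (median 0.15), with Kdr at 0.45 ± 0.22 and Egfl7 at 0.53 ± 0.31. Meninges genes (14 of 16, median −0.39) and choroid plexus genes (13 of 17, median −1.86) had negative ones. The meninges score was alike in both genotypes at 3 h (2.76 ± 0.50 log2 CPM in het, 2.78 ± 0.38 in WT), so the difference came from the home cage (2.90 ± 0.37 and 2.51 ± 0.31). The glucocorticoid-induced genes had a median interaction of −0.03 over 32 genes, with Plin4 at −0.36 ± 0.63 and Mertk at −0.03 ± 0.18, both named after their values were seen. The smallest p belonged to Tnfsf13b (2.11 ± 0.58), Tacr1 (−1.57 ± 0.45) and the elongation factor gene Elof1 (0.49 ± 0.14). Both interactions use the same home-cage libraries, so the return of Tnfsf13b and of the meninges genes is not independent of the values at 1 h.

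No gene passed for this interaction, with 0 of 14899 in edgeR (210 at an unadjusted p below 0.05), 0 in DESeq2 and 0 in limma voom. Camera adjusted p was 0.00696 for chaperones, 0.00826 for meninges, 0.0130 for oxidative phosphorylation and 0.0354 for endothelial markers and for choroid plexus, and with an estimated correlation 0.687 to 0.789. The chaperone call was lost without home-cage het replicate 2 (0.0663) and, within the 15 libraries low in both technical measures, stood at 0.980 with the sign turned. The oxidative phosphorylation, meninges, endothelial and choroid plexus calls were lost in 5, 4, 10 and 11 of 20 refits that leave out a library, at up to 0.712, 0.266, 0.696 and 0.993. The other 24 lists had camera adjusted p from 0.103 to 0.763. With no gene called in the averaged response at 3 h, the response size was taken over lists, at 0.03 for immediate early genes and −0.03 for glucocorticoid-induced genes.

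Most immediate early genes of WT mice had lower values at 3 h than at 1 h. Of 46, 37 had lower values at 3 h (median log2 fold change −0.28) and 10 passed over the list alone, all lower. Junb fell from 106 ± 13.2 to 58.7 ± 3.87 CPM (SD, n = 4 and 5, −0.85 ± 0.15 SE) and Egr2 from 4.44 ± 0.759 to 1.06 ± 0.174 CPM (−2.06 ± 0.37), each with an edgeR adjusted p of 0.0436. Fos stood at 3.54 ± 1.01 against 13.4 ± 2.70 CPM (−1.92 ± 0.40), Egr4 at 43.3 ± 16.9 against 108 ± 9.04 CPM (−1.33 ± 0.34) and Fosb at 3.97 ± 1.16 against 7.95 ± 0.954 CPM (−1.01 ± 0.28). Dusp5 (−0.80 ± 0.21), Egr1 (−0.69 ± 0.19), Dusp6 (−0.50 ± 0.16), Midn (−0.42 ± 0.13) and Jun (−0.32 ± 0.11) were lower as well. These 8 were named after their values were seen. Of the glucocorticoid list, which did not pass (median 0.07 over 32), Nfkbia stood at −0.49 ± 0.16 and Rhob at −0.45 ± 0.14. Oxidative phosphorylation genes had higher values at 3 h in 59 of 72 cases (median 0.14), with Uqcrq at 303 ± 48.4 against 230 ± 13.9 CPM and Cox7a1 at 7.01 ± 2.38 against 3.14 ± 0.738 CPM. In het mice 32 of 46 immediate early genes had lower values at 3 h (median −0.10), and Egr2 (0.662 ± 0.368 against 2.65 ± 1.33 CPM, −1.96 ± 0.40) and the endothelial early gene Apold1 (−1.06 ± 0.27) passed over the list alone. So did Sv2c (26.3 ± 4.52 against 43.0 ± 7.08 CPM, −0.71 ± 0.15) and Plin4 (1.70 ± 0.43) over theirs. Jag1 stood at 9.34 ± 1.63 against 5.59 ± 1.30 CPM in het mice (0.74 ± 0.16), Fos at −1.17 ± 0.37 and Junb at −0.31 ± 0.14, the last pair named after their values were seen. Setd5 stood at −0.16 ± 0.10 in WT and 0.03 ± 0.10 in het mice.

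Of 14899 genes edgeR called 2 in WT mice, Junb and Egr2 (851 at an unadjusted p below 0.05), and 0 in het mice (528), DESeq2 called 3 and 0, and limma voom 4 and 1, the last being Sv2c. Leaving out any 1 of the 9 WT libraries compared left 0 genes in edgeR, as did an adjusted p of 0.01, a minimum count of 50, library-size scaling, surrogate variables, the 15 libraries low in both technical measures and leaving out the 3 libraries with choroid plexus transcripts. With a minimum count of 50 Egr2 was filtered out before testing, so only Junb of the pair was tested again. Camera adjusted p of the immediate early genes was 2.74e-15 in WT mice (adjusted p = 0.0635 with an estimated correlation, 0.0415 in fry) and 0.00415 in het mice (0.657 with an estimated correlation). The het call was lost without het replicate 3 or 4 of 1 h (0.162 and 0.454) or het replicate 1 or 2 of 3 h (0.0830 and 0.123). Their mean was 4.23 ± 0.15 log2 CPM at 3 h (n = 5) and 4.65 ± 0.05 at 1 h (n = 4) in WT mice, with a two-sided exact permutation p of 0.0159 (adjusted p = 0.138). Oxidative phosphorylation had a camera adjusted p of 5.76e-07 in WT mice and did not pass with an estimated correlation. Choroid plexus genes passed in both genotypes (camera adjusted p = 0.0407 in WT, 0.00194 in het), with medians of 1.87 and 1.93. With an estimated correlation the adjusted p was 0.949 and 0.657. The calls ended without WT replicate 2 of 3 h or WT replicate 2 of 1 h (0.919 and 0.195) and without het replicate 4 of 3 h (0.737). In het mice oligodendrocyte markers (21 of 25 higher, median 0.11, with Tspan2 at 0.35 ± 0.16 and Myrf at 0.31 ± 0.16) and ribosomal proteins (40 of 70 lower, median −0.05) also passed, at camera adjusted p of 0.0299 and 0.0336, with adjusted p = 0.657 under an estimated correlation. They were lost in 5 and 6 of 10 refits that leave out a library. The other 26 lists in WT mice had camera adjusted p from 0.0539 to 0.987, and the other 25 in het mice from 0.0969 to 0.918.

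**Figure D5:**
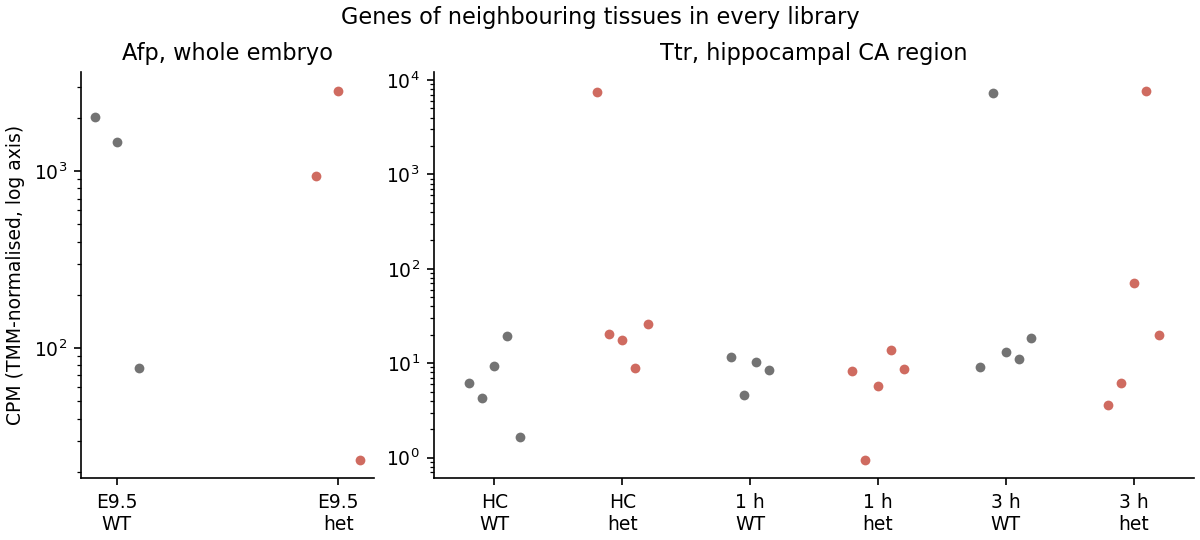
Afp, a yolk sac gene, in every embryo library (left) and Ttr, a choroid plexus gene, in every hippocampal library (right), in CPM on log axes. Points are libraries; Afp runs from 23.4 to 2846 CPM, and Ttr stands at 7348 CPM or more in 3 hippocampal libraries and at 70.6 CPM or less in the other 26.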

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

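All tests in this part other than those of the differences between groups and the splits of the libraries were chosen after the result was seen. In 84 tests of the highest or lowest library of a group, 11 libraries or scores lay apart from the others by Dixon's test. Chance marks about 1 in 20, or 4.2, but the tests were not independent. Ttr and the choroid plexus score, which includes Ttr, marked the same 3 libraries. The count is thus no measure of an excess over chance. At 3 h in WT mice, replicate 5 had Fos at 5.30 CPM (others 2.82 to 3.45) and Plin4 at 2.56 CPM (others 7.12 to 7.94), and replicate 1 had an immediate early gene score of 3.97 log2 CPM (others 4.24 to 4.34). Home-cage het replicate 2 had Egr2 at 2.15 CPM (others 0.269 to 0.807), and het replicate 2 at 3 h had Setd5 at 131 CPM (others 144 to 149).

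Choroid plexus transcripts were far above the rest of the group in 3 hippocampal libraries. Ttr stood at 7348 CPM in WT replicate 2 at 3 h (others 9.01 to 18.6), 7444 CPM in home-cage het replicate 1 (others 8.91 to 25.7) and 7710 CPM in het replicate 4 at 3 h (others 3.61 to 70.6), with choroid plexus scores of 5.79 (others 1.66 to 2.20), 5.90 (others 1.52 to 2.33) and 5.98 log2 CPM (others 1.70 to 2.44). Of the 17 markers of that list tested, 14 were higher in each of these libraries than in any of the other 26. Ttr, by which the libraries were picked, is among them, and Tmem212, Rarres2 and Ccdc153 are not. All 7 markers that the filter had left out were higher too. The filter drops genes that are high in only 3 libraries, so these 7 are no independent test. Choroid plexus tissue in the dissected samples would go with these values but was not tested independently. No group held more than 1 library with these high levels, so they were not a trait of all libraries of any genotype or training state. An influence of genotype or training state on how often they occur cannot be excluded, as 3 libraries are too few to test it.

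Tests of the difference between genotypes marked the lists that passed for the interactions. At 1 h these were immediate early genes (median −0.21), choroid plexus (−1.91), meninges (−0.40) and oxidative phosphorylation (0.11). At 3 h they were chaperones (−0.16), choroid plexus (−1.86), endothelial markers (0.15), meninges (−0.39) and oxidative phosphorylation (−0.11). Both interactions share the home-cage libraries, so a list marked at both times is not marked by independent data. On the strand opposite to the gene, which no comparison used, lay a median of 4.50% of stranded gene counts (4.33% to 4.83% over 35 libraries).

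The negative interaction of immediate early genes at 1 h was weighed against the technical class of the libraries and against a single library. A single library cannot be told apart from a genotype effect, as the median interaction nearest to 0 was −0.12, without het replicate 1 at 1 h, and the interaction of the list score was then −0.17 ± 0.16 (SE). For the class, that interaction was −0.12 ± 0.22 in the 10 libraries low in both measures, −0.25 ± 0.17 in all 19 and −0.20 ± 0.19 with class as a term. The class cannot be told apart from a genotype effect, as all 4 WT libraries at 1 h belong to 1 class and the errors are wide.

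The higher neuronal genes in het embryos were weighed against sex, yolk sac share and the share of neural tissue. Sex cannot be told apart from genotype, since the median of 0.49 among the 4 embryos with Y-linked expression sets 3 het embryos beside a single WT embryo. With the yolk sac score as a linear covariate the median was 0.53, and the neuronal score still differed by 0.53 ± 0.07 (SE over embryos). These values argue against a linear effect of that score as the whole cause. They do not exclude yolk sac share, as the fit held 6 embryos and left sex out. Its score also mixes yolk sac genes with decidual ones such as Prl8a2, which ran otherwise. A larger share of neural tissue, alike for all its cells, cannot be told apart either. The progenitor median lay below the neuronal one (difference −0.24, SE 0.10 over genes), but the scores of both lists differed alike between genotypes (difference 0.01, SE 0.34 over embryos). An advance in embryonic stage or a shift from progenitors to neurons was not tested.

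Other splits of the same libraries into groups of the same sizes were refitted, and each count includes the real split. A real count of 0 is reached by every split, so such a count is no test of chance. In the embryo this was 10 of 10 splits (0, highest other 210). As large a median came in 2 of 10 for the cardiac list (−0.27, largest other −0.40) and in 1 of 10 for the neuronal list (0.57, largest other −0.36). With 10 splits no share can lie below 0.05. For genotype in the hippocampus, 100 of 100 splits reached the real 0 calls by construction, in the home cage (highest other 0), at 1 h (5), at 3 h (0), in the average (1) and for the interactions at 1 h (2) and 3 h (1). For the median interaction of immediate early genes at 1 h (−0.21, largest other 0.41) it was 19 of 100, so chance cannot be excluded for it.

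For training, a result that fewer than 5 of 100 splits reached was taken as rare, with no adjustment over the results tested. The splits ignored technical class, which all 4 WT libraries at 1 h share. A rare result therefore does not part training from class. Rare were the calls at 1 h against home cage in WT mice (2 splits, real 1, highest other 1). So were the calls between 3 h and 1 h in WT mice (1 split, real 2, highest other 1). The median of immediate early genes in that comparison was rare too (4 splits, −0.28, largest other 0.32). For the score of that list, the exact permutation test gave an adjusted p of 0.138 there. Chance cannot be excluded for the median of immediate early genes at 1 h in WT (5 splits, 0.25, largest other 0.32) or het mice (52 splits, 0.12, largest other −0.27), nor for the glucocorticoid list at 3 h in WT (6 splits, 0.23, largest other 0.31) or het mice (15 splits, 0.20, largest other −0.28). The real count of 0 calls, again no test of chance, was reached in 100 of 100 splits at 1 h in het mice (highest other 1), at 3 h in WT (1) and het mice (1) and between 3 h and 1 h in het mice (2).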

How the results depend on the processing

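Alternatives by library class, without the choroid plexus libraries, with a yolk sac covariate, of the 4 Y-expressing embryos alone and by the glucocorticoid list were chosen after seeing the data. For moved or reversed values the cause was not tested. Counts of calls changed as follows, and other alternatives but the replicate block (below) left them as reported. In embryos (0), DESeq2 gave 2, the 4 Y-expressing embryos (1 of them WT) 1, and leaving out a library 0 to 6. The 6, without WT replicate 2, were Ddx3y, Eif2s3y, Uty, Kdm5d, Xist and a Y-chromosomal gene model, as sex then parted with genotype in full. For the averaged genotype effect (0), DESeq2 gave 3, limma voom 4, surrogate variables 5, the class term 2, library size only 1 and leaving out a library 0 to 1. At 3 h het against WT (0), limma voom gave 1. For 1 h in WT mice (1), DESeq2 gave 5, limma voom 14, surrogate variables 2, no filter 2, and adjusted p 0.01, a minimum count of 50 and the 15 libraries low in both measures 0 each, with 0 to 3 when a library was left out. A minimum count of 50 removed Egr2 before testing, here and for 3 h against 1 h, so it is no test of that gene. For 1 h in het mice (0), leaving out a library gave 0 to 1. For 3 h against 1 h in WT mice (2), DESeq2 gave 3, limma voom 4, only the groups compared 5, the class term 1, and adjusted p 0.01, library size only, a minimum count of 50, surrogate variables, the 15 libraries low in both measures and leaving out the 3 choroid plexus libraries 0 each, as did leaving out any 1 library. In het mice (0), limma voom gave 1. Of 372 list tests, the sex-linked list left out, 51 passed in camera, 1 with an estimated correlation and 1 in fry. Of the 51 calls in camera, 39 ended in at least 1 alternative other than a left-out library, with the estimated correlation and fry not counted. They were 24 in the 15 libraries low in both measures, 20 with tissue covariates, 17 in the 9 libraries with a high share outside genes, 15 without the choroid plexus libraries, 14 with a minimum count of 50, 10 with surrogate variables, 8 with the block, 7 with the class term and at most 3 in any other. Of those 9 libraries only 1 was het at 3 h, so comparisons with that group rest on a single library there. The tissue covariates are the choroid plexus and dentate gyrus scores. Calls of those lists that ended with these covariates were thus bound to weaken and are no test. With the estimated correlation and fry again not counted, 10 calls ended in none of the alternatives and refits run for them. They were 5 in the embryo (neuronal, cardiac, progenitor, neural crest, cholesterol) and 5 in WT mice (immediate early and glucocorticoid at 1 h, glucocorticoid at 3 h, immediate early and oxidative phosphorylation at 3 h against 1 h). Of these 10, only the glucocorticoid list at 3 h passed with an estimated correlation. In fry only the immediate early genes at 3 h against 1 h passed.

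Replicate numbers did not pair the libraries throughout. The lowest correlation of same-numbered libraries was −0.30 to 0.02 over the comparisons, and in none did all libraries correlate best with their own number. In the home-cage genotype comparison 6 of 10 libraries did. Some shared structure is there, as up to 4 of 5 pairs correlated above 0.1, and in 3 of the 6 hippocampal groups technical class followed replicate number alike. A replicate block gave 3 calls for 1 h in WT mice, 1 for 3 h against 1 h in WT mice and a response size at 1 h of −0.29 (over Junb, Egr2 and Nfkbia), and changed no other count of calls. Genes at an unadjusted p below 0.05 in edgeR rose with the block in every hippocampal comparison. They rose from 698 to 1421 for het against WT at 1 h and from 512 to 1151 for the interaction at 1 h. In the embryo they fell from 317 to 266. With the block camera no longer passed endothelial markers (adjusted p 0.0767), astrocyte markers and p53 targets (0.0782 each) and choroid plexus (0.136) in the average. The same held for choroid plexus at 3 h against 1 h in WT mice (0.0772) and in the interactions at 1 h (0.329) and 3 h (0.171), and for endothelial markers in the interaction at 3 h (0.0635).

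Response size at 1 h (−0.55 over Egr2, Junb and Fos) was −0.55 with DESeq2 size factors, −0.42 with the class term, −0.40 without the choroid plexus libraries and −0.71 to −0.22 without single libraries. Both ends used these 3 genes, while other refits used the 2 to 4 genes called in them, and the class term and the fit without the choroid plexus libraries Egr2 and Junb. Over lists it was −0.18 for immediate early genes (−0.29 to −0.11 without single libraries, −0.10 with the class term). For glucocorticoid-induced genes it was −0.05 (−0.14 to 0.02 without single libraries, −0.05 with the class term). The glucocorticoid value turned sign without home-cage het replicate 1 (0.02) or 4 (0.01), without the choroid plexus libraries (0.02) and in the 15 libraries low in both measures (0.04). In the 15 libraries low in both measures no gene was called, and the immediate early list stood at −0.01. It was not run with other tools, filters, surrogate variables or covariates. At 3 h the immediate early list (0.03) turned to −0.01 without the choroid plexus libraries and spanned −0.06 to 0.09 without single libraries, with −0.06, −0.04, −0.03, −0.01, −0.01 and −0.00 among them. The glucocorticoid list (−0.03) turned to 0.07 in the 15 libraries low in both measures and spanned −0.10 to 0.02. Choroid plexus turned sign with tissue covariates in the home cage (camera adjusted p 0.935), the average (0.797), 1 h in het mice (0.852), 3 h against 1 h in het mice (0.605) and the interaction at 1 h (0.875). Those covariates include the list's own score, so these values are no test of it. In the 15 libraries low in both measures it turned in the home cage (0.590), at 3 h in WT mice (0.696), 3 h against 1 h in WT mice (0.892) and the interaction at 3 h (8.37e-05). Of the 3 libraries with high choroid plexus genes, those 15 hold only het replicate 4 of 3 h, so the last value rests on that library. Leaving out home-cage het replicate 1 turned the interaction at 3 h too (0.960), and refits without single libraries spanned 9.67e-07 to 0.993. Chaperones turned for the interaction at 3 h in those 15 (0.980). In the 9 libraries with a high share outside genes, immediate early genes at 1 h in het mice (0.893), ribosomal proteins at 3 h in WT mice (0.918) and endothelial markers for the interaction at 3 h (0.610) turned. The last rests on a single het library at 3 h, assumed to vary like the other groups. Over all libraries and without the class term no gene was called at 3 h, so no response size was formed there. Where a refit called genes at 3 h, it was −0.55 over Plin4 (without WT replicate 5 of 3 h), −0.18 over Plin4 (without het replicate 2 of 3 h), 0.07 over Mertk, Plin4 and Xdh (without home-cage het replicate 4) and −0.01 over Mertk (class term).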

Other observations

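Transcripts of the visceral yolk sac ran over a wide range among the 6 embryos, though the labels say that the yolk sac was removed. Afp, a fetal serum protein gene, stood at 2009, 1466 and 76.7 CPM in WT replicates 1 to 3 and at 942, 2846 and 23.4 CPM in het replicates 1 to 3. Apob, an apolipoprotein gene, stood at 144, 85.6 and 7.21 CPM and at 54.3, 184 and 0.673 CPM. The prolactin family gene Prl8a2, a decidual transcript, ran otherwise, at 7.81, 1.80 and 31.7 CPM and at 0.591, 6.16 and 123 CPM.

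Snhg6, a host gene of small nucleolar RNA, and the protein-coding genes Crtc2, Mrps28, Sdhd, Cog3, Adam9 and Pank4 ranged widely between libraries of both tissues. In the hippocampus Snhg6 ran from 1.72 to 51.9 CPM and Sdhd from 2.53 to 44.9 CPM over 29 libraries, and in the embryo from 3.91 to 50.2 CPM and from 3.15 to 43.2 CPM over 6. All 29 hippocampal libraries expressed Xist, at 202 to 333 CPM, with at most 1 Y-linked count.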
